A study of Novosphingobium resinovorum with 8 samples.

How the data were processed

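Total RNA from 8 cultures of Novosphingobium resinovorum SA1 was sequenced, 2 independent biological replicates for each of 4 groups. The groups cross the substrate (10 mM glucose with 10 mM ammonium chloride, or 10 mM sulfanilic acid with no other nitrogen source) with the growth phase (exponential or late stationary). All media held 25 mM MOPS and 25 ug/ml Sm, and the cultures were kept at 28 degrees C. The carbon and the nitrogen source therefore change together between the substrates.

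The files hold 3 comparison tables made by the authors: Glc_S against Glc_E, SA_E against Glc_E, and SA_S against SA_E. The authors used edgeR, per the submitters' processing notes, with no version given; the aligner, the counting tool, the genome build and gene lengths are not given in the sources used here. The log2 fold changes were computed and normalized by the authors, by a method that the file headers do not state. The FDR-adjusted p-values are those of the authors' test, per the file headers. The RPKM columns hold the authors' value per group, called a mean in the headers except that of Glc_S. The authors' call column is 1 or -1 exactly where the absolute log2 fold change is at least 2 and the adjusted p is under 0.001. No value per library is in these tables, so the spread between replicates, tests of single libraries and fits with left-out libraries are not given here.

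Of 6113 listed genes, the 116 without values were left out and 5997 were used in all 3 comparisons, with no further filter. A gene was called higher or lower where the authors' adjusted p was below 0.05. The unadjusted p-values were recovered by inverting the Benjamini-Hochberg adjustment over the 5997 genes, which returns only the largest p that a run of tied values allows. They were used for adjustment over a gene list alone, for adjustment after filters, and for genes with opposite phase changes, where the larger p of the 2 changes of a gene was adjusted over all genes. A further test of the difference between the 2 phase changes took standard errors from the fold changes and p-values under a normal approximation; it was added after the data were seen, and 1151 genes with an adjusted p listed as 1 have no such error and cannot be called by it. The opposite-direction test carries the phase comparison; the normal approximation treats the 2 changes as independent, as they share no library.

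The 30 gene lists were fixed before the files were seen, as word patterns applied to the product names. Each list was tested for an excess or a lack of higher calls and of lower calls against all other tested genes with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 60 tests per comparison. List medians were set beside 10000 random lists matched on expression in 20 bins. The patterns caught wrong products in 11 lists, so lists without these products were added as an alternative. Cell division and DNA replication went from 73 to 39 genes by this, and DNA repair and SOS from 62 to 34. Genes were named by a rule fixed beforehand: per comparison, the 7 highest and 7 lowest fold changes among called genes with an annotated product, and up to 4 members with the largest fold change of each list with an excess of calls. The lists on aromatic degradation, ribosomal proteins, sulfur metabolism and nitrogen metabolism were treated so whatever their result, and every aromatic degradation gene could be named in SA_E against Glc_E. The planned minimum level and agreement of both libraries needed values per library and were not applied. All stretches of neighbouring genes, the genes named from them outside the rule, and genes followed from the comparison that named them into another, were chosen after their values were seen. The values of 1 gene that the rule named are not reported here. SA_S and Glc_S are not compared in any deposited table, so their RPKM ratios were taken with a pseudocount of 1 and no test.

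The depth was estimated from the RPKM values, since a gene with few reads can only take values in steps of 1 read, on the assumption that gene lengths are multiples of 3. For 1322 genes above 0 and under 15 RPKM in Glc_S, any number of reads up to 20 was tried with a single library size. For 99.6% of them some number gave a gene length within 0.01 units of 3 bases of a multiple of 3, against 25.9% by chance. The other columns needed 2 library sizes each, which placed 89.3% of 680 low genes in Glc_E, 84.8% of 686 in SA_E and 94.2% of 673 in SA_S. The range searched was set after a first search had returned a multiple of the SA_E unit. The summed estimates were 1408541 reads for Glc_E, 376572 for Glc_S, 1509852 for SA_E and 530037 for SA_S. Errors and intervals from these depths cover counting error only.

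The alternatives were an adjusted p of 0.01, a minimum log2 fold change of 1, filters at 1 and 10 RPKM, genes at 0 left out, the authors' own call, RPKM sums made equal, the median fold change set to 0, pseudocounts of 0.1 and 5, list members thinned to the first of neighbouring genes, and list tests within replicons. All were chosen after the data were seen except the adjusted p of 0.01, the log2 minimum, the filter at 1 RPKM and the pseudocounts. For rescaled fold changes 2 versions of the standard error were tried. The first floored every error and lost calls even without a shift, 1040 instead of 1188 higher genes in Glc_S against Glc_E, so the second, which keeps the authors' calls at no shift, was used; both are reported. The steps were run on simulated data: 0 of 87 null list tests and 3 of 3 planted lists were called, 100 of 100 planted opposite genes were found with 0 false ones, and the difference test found 195 of 200 with 8 false. The null lists were drawn only from genes without a planted change, the planted changes were strong, and genes were independent. These counts therefore check the code only, and give no false-call rate for the real data. The difference test was simulated with normal noise, which it assumes, so its counts do not check the approximation on the authors' p-values. Library sizes were recovered for 3 simulated columns, with a largest relative error of 4.3e-05%. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.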

Results

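Transcripts of the bacterium Novosphingobium resinovorum SA1 were measured by RNA sequencing in 8 libraries, 2 independent cultures in each of 4 groups. Cells grew on glucose with ammonium chloride, or on sulfanilic acid, a sulfonated aromatic amine that served as both carbon and nitrogen source. They were sampled in exponential phase (Glc_E and SA_E) or in late stationary phase (Glc_S and SA_S). The genome has a chromosome and 4 plasmids, pSA1 to pSA4. Fold changes, adjusted p and RPKM (reads scaled to gene length and sequencing depth) are those of the authors' deposited tables, which list 6113 genes, 5997 of them with values. The tables hold no value per library, so no spread between the 2 cultures can be given, and a gene is called higher or lower where the authors' adjusted p lay below 0.05. Numbers after a gene are log2 fold changes unless another quantity is named, and stretches of neighbouring genes were chosen after their values were seen.

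The depth per library is not given in the sources used here, and it was estimated from the steps between low RPKM values, which rests on gene lengths being multiples of 3. The estimates were 756465 and 652076 reads for the Glc_E pair, 797864 and 711988 for SA_E, and 269811 and 260226 for SA_S. The Glc_S values lay on a single step that matches 376572 reads, either from 1 library or from pooled reads. RPKM ratios followed the fold changes as closely in Glc_S against Glc_E (SD of the log2 difference 0.0570) as in SA_E against Glc_E (0.0551) and SA_S against SA_E (0.0563). If the column holds 1 library, the calls of Glc_S against Glc_E and the phase comparison may thus rest on 1 Glc_S culture. Which case holds is not known. A single read of a gene of 900 bases would thus count 0.789 RPKM in Glc_E, 2.95 in Glc_S, 0.736 in SA_E and 2.10 in SA_S. Genes listed at 0 numbered 66 in Glc_E, 366 in Glc_S, 20 in SA_E and 164 in SA_S. Weakly expressed genes were therefore harder to detect in stationary phase, and no fold is given against a group listed at 0.

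The comparison of SA_E with Glc_E asked how actively growing cells on the xenobiotic differ from cells on the control sugar. On sulfanilic acid, genes of the sulfocatechol branch of its breakdown rose on plasmid pSA3. Per the authors' deposited table, maleylacetate reductase (BES08_30505, 6.31, adjusted p = 7.7e-169), which yields 3-oxoadipate, was listed at 124 RPKM in Glc_E and 9653 in SA_E. Nearly all ribosomal protein genes fell, as did the 4 genes of a cytochrome o oxidase and 7 genes in 2 stretches of sulfate assimilation. Of 5997 genes, 951 were higher and 1126 lower on sulfanilic acid, 34.6% together. The authors' own call, which needs a log2 fold change of at least 2 and an adjusted p under 0.001, gave 256 and 181. Making the RPKM sums of the groups equal shifted fold changes of this comparison by 0.05, those of Glc_S against Glc_E by -0.18 and those of SA_S against SA_E by -0.42 (log2).

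All 15 genes from BES08_30470 to BES08_30540 on pSA3 were higher on sulfanilic acid, with a median of 4.44. They included, in the authors' deposited table, 3-sulfo-cis,cis-muconate cycloisomerase (BES08_30495, 6.56), 4-sulfomuconolactone hydrolase (BES08_30500, 6.08) and both subunits of sulfocatechol 3,4-dioxygenase, the ring-cleaving enzyme (BES08_30515, 4.44; BES08_30520, 4.57). A TauE/SafE sulfite exporter of the same stretch (BES08_30490) was at 3.87 with an adjusted p of 2.1e-56 in the authors' deposited table. The stretch held 0.224% of the RPKM in Glc_E and 6.79% in SA_E. Another pSA3 stretch of 6 genes, BES08_30690 to BES08_30725, holds a ring-hydroxylating oxygenase with its electron carriers, and all 6 genes were higher. An IS110 family transposase (BES08_30705) is among the 6. The authors' deposited table lists ferredoxin (BES08_30690, 3.33), ferredoxin reductase (BES08_30695, 3.56), a gene annotated as glutamine synthetase (BES08_30720, 2.23) and the oxygenase alpha subunit (BES08_30725, 1.78). The share of these 6 genes in the RPKM went from 2.35% to 12.9%. Both subunits of a pSA3 benzoate 1,2-dioxygenase were higher too, at 2.79 (BES08_30344) and 2.12 (BES08_30345) in the authors' deposited table.

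**Figure D1:**
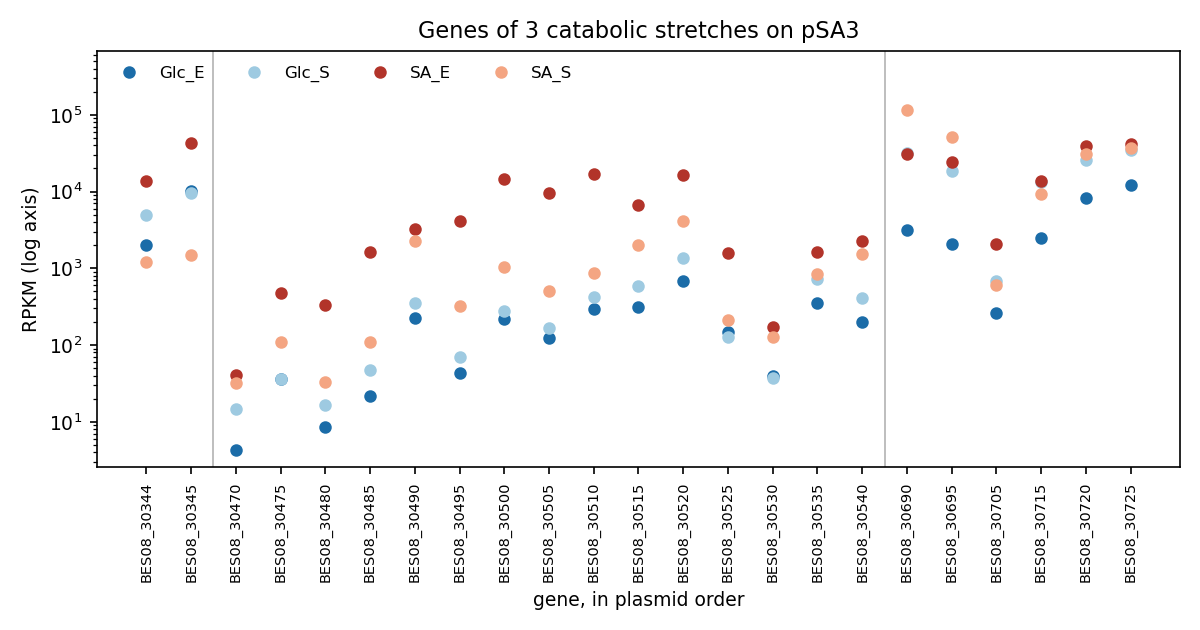
The authors' RPKM of the genes in the 3 catabolic stretches of plasmid pSA3, on a log axis, in Glc_E, Glc_S, SA_E and SA_S; each point is a group value with no spread. Sulfocatechol genes lie far higher in SA_E than in Glc_E, with a median of 2278 against 149 RPKM.

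Of the aromatic degradation list, 23 of 52 genes were higher and 8 lower (23 and 8 adjusted over the list alone). Higher calls were more frequent than among other genes, 44.2% against 15.6% (Fisher's exact test, two-sided, adjusted p = 9.2e-06). Outside the stretches above, the authors' deposited table lists higher values for a ring-hydroxylating oxygenase alpha subunit (BES08_18230, 3.27), biphenyl 2,3-dioxygenase (BES08_18145, 1.66) and a benzoate 1,2-dioxygenase small subunit (BES08_19585, 3.34) of pSA1. The 8 lower members included the protocatechuate branch of pSA1, which cleaves protocatechuate formed from 4-hydroxybenzoate. The authors' deposited table gives 4-hydroxybenzoate 3-monooxygenase (BES08_24955, -4.32, adjusted p = 2.0e-43), protocatechuate 3,4-dioxygenase subunit beta (BES08_24950, -3.57) and 3-carboxy-cis,cis-muconate cycloisomerase (BES08_24940, -2.88). Catechol 1,2-dioxygenase of pSA1 (BES08_19595) did not pass, at 0.27 with adjusted p = 0.917 in the authors' deposited table.

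The increase was not limited to these stretches of pSA3. Of its 314 tested genes, 164 were higher and 9 lower, so 52.2% were higher, against 11.3% on the chromosome, 17.0% on pSA1, 19.3% on pSA2 and 12.7% on pSA4. The median fold change of pSA3 genes was 1.14 (quartiles 0.30 and 2.26). The share of all RPKM on pSA3 was 6.77% in Glc_E, 22.1% in Glc_S, 31.8% in SA_E and 29.4% in SA_S, and that of the chromosome 82.8%, 57.1%, 54.0% and 51.6%. Most of the pSA3 share in SA_E lay in the sulfocatechol, oxygenase and benzoate dioxygenase stretches, with 6.79%, 12.9% and 4.87% of all RPKM. In Glc_E they held 0.224%, 2.35% and 0.996%. The share by itself therefore does not show a rise outside these stretches, unlike the counts of genes. Among pSA3 genes, the authors' deposited table lists a molybdopterin oxidoreductase (BES08_29795, 7.52, adjusted p = 1.4e-81) with 5.53 RPKM in Glc_E and 997 in SA_E.

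**Figure D2:**
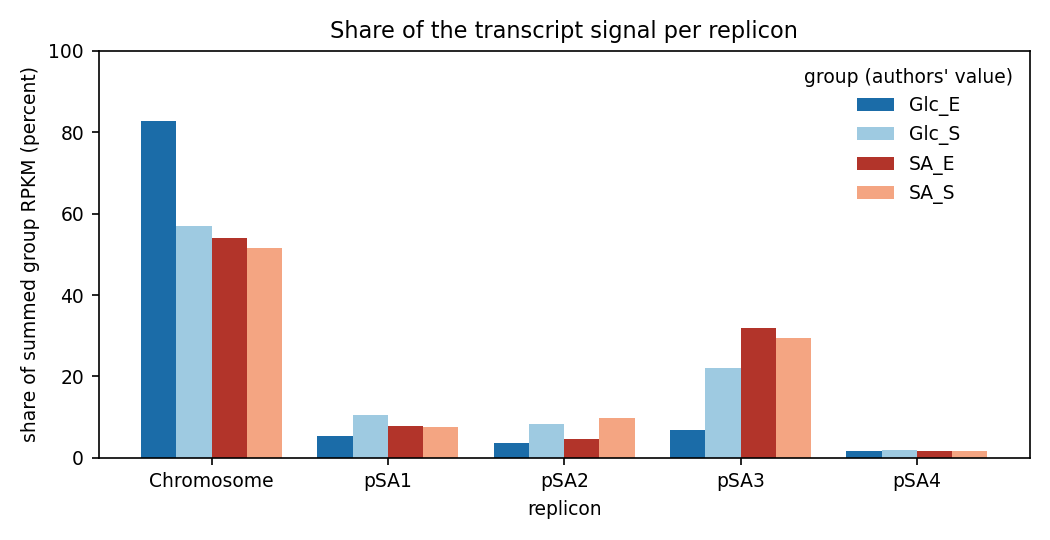
The share of the authors' summed RPKM (percent, axis from 0) held by the chromosome and each of the 4 plasmids in Glc_E, Glc_S, SA_E and SA_S; each bar is a group value with no spread. Plasmid pSA3 holds 6.77% in Glc_E and 31.8% in SA_E, where most of it lies in the 3 catabolic stretches (6.79%, 12.9% and 4.87% of all RPKM).

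The 3 highest named fold changes came from pSA1, where 11 neighbouring genes, BES08_23650 to BES08_23700, were all higher by 4.31 to 8.68. In the authors' deposited table this stretch holds a monooxygenase (BES08_23655, 8.68), a GlcG protein (BES08_23660, 8.52), a glyoxalase (BES08_23665, 8.22), an amidohydrolase (BES08_23650, 7.40), 5-carboxymethyl-2-hydroxymuconate isomerase (BES08_23670, 7.07) and a TonB-dependent receptor (BES08_23675, 6.71). The amidohydrolase went from 36.3 to 6046 RPKM, per the authors' deposited table. A chromosomal stretch of 18 genes annotated around quinoprotein dehydrogenases, which pass electrons from alcohols or aldehydes to cytochrome c, was higher throughout (BES08_15985 to BES08_16070). The authors' deposited table lists its cytochrome c-550 PedF (BES08_16025, 5.38) and an aldehyde dehydrogenase (BES08_15985, 4.42).

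The translation machinery was lower on sulfanilic acid. Of the ribosomal protein list, 0 of 53 genes were higher and 51 lower (0 and 51 adjusted over the list alone), with a median of -2.02. The authors' deposited table lists 30S ribosomal protein S12 (BES08_09305, -2.93, adjusted p = 1.7e-50), 50S ribosomal protein L9 (BES08_01790, -2.93), L3 (BES08_09275, -2.91) and L2 (BES08_09260, -2.89). Aminoacyl-tRNA synthetases, which charge tRNAs, counted 0 higher and 21 lower of 21 (0 and 21 adjusted over the list alone), and translation factors 1 higher and 14 lower of 16 (1 and 14 adjusted over the list alone). As listed in the authors' deposited table, tyrosine tRNA ligase (BES08_03780, -2.51) and elongation factor Ts (BES08_01205, -2.84) fell, while an initiation factor IF-1 (BES08_16640, 1.83) rose. Of the RNA polymerase and elongation list, 0 of 12 genes were higher and 9 lower (0 and 9 adjusted over the list alone), among them the RNA polymerase alpha subunit (BES08_09145, -1.89) in the authors' deposited table. Chaperones and proteases counted 0 higher and 15 lower of 27 (0 and 17 adjusted over the list alone), with the HslU ATPase subunit (BES08_23725, -2.18) and DnaK (BES08_03910, -1.99) in the authors' deposited table. Lower calls were enriched in all 5 lists, with adjusted p of 2.0e-33, 1.4e-14, 1.0e-07, 2.2e-04 and 1.4e-04 in that order.

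Central metabolism and respiration were lower as well. Of the TCA cycle and glyoxylate shunt list, 2 of 20 genes were higher and 15 lower (2 and 16 adjusted over the list alone), of ATP synthase 0 higher and 8 lower of 8 (0 and 8 adjusted over the list alone), and of the respiratory chain 7 higher and 21 lower of 39 (7 and 24 adjusted over the list alone); lower calls were enriched (exact test, adjusted p = 1.1e-06, 1.1e-05 and 9.1e-06). In the authors' deposited table, malate dehydrogenase (BES08_09050, -2.27) and succinate-CoA ligase subunit alpha (BES08_09055, -2.20) fell, and a pSA3 isocitrate lyase (BES08_30740, 2.42) rose. The 4 subunits of the cytochrome o ubiquinol oxidase, a terminal oxidase, were all lower, led by subunit II (BES08_12950, -4.28, adjusted p = 1.5e-74) in the authors' deposited table. Of glucose catabolism, 6 of 40 genes were higher and 16 lower (7 and 16 adjusted over the list alone) (exact test, adjusted p = 0.00667 for lower calls). Its falling members included enzymes of the Entner-Doudoroff route, phosphogluconate dehydratase (BES08_09980, -3.14) and glucokinase (BES08_09985, -3.11), in the authors' deposited table, whereas a pSA1 glucose dehydrogenase (BES08_21100, 3.25) rose. Among the lowest values of the authors' deposited table were a glucose/galactose transporter (BES08_22550, -4.81, adjusted p = 4.3e-79), an alanine racemase (BES08_19720, -4.81) and a fructose PTS transporter subunit (BES08_21275, -4.77). An amino acid dehydrogenase (BES08_00560, -4.64), a ligand-gated channel (BES08_17955, -4.59) and an ABC transporter ATP-binding protein (BES08_17950, -4.51) were also among them in the authors' deposited table.

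Sulfanilic acid carries sulfur and nitrogen, and genes for both elements went both ways. Of sulfur metabolism, 5 of 29 genes were higher and 7 lower (5 and 7 adjusted over the list alone), and of nitrogen metabolism 6 higher and 10 lower of 29 (6 and 10 adjusted over the list alone); neither list had more calls than other genes (lowest adjusted p by the exact test 0.693 and 0.140). Sulfate assimilation was the falling part in the authors' deposited table: sulfate adenylyltransferase small subunit (BES08_04950, -4.57, adjusted p = 1.1e-60), adenylyl-sulfate kinase (BES08_04945, -3.63) and sulfite reductase (BES08_00835, -3.33). For nitrogen, the authors' deposited table lists the ammonia channel protein (BES08_15455, -3.58, adjusted p = 3.9e-31), a urea carboxylase-associated protein of pSA1 (BES08_21615, 4.05) and another of pSA2 (BES08_26220, 3.57). Of flagellum and chemotaxis genes, 6 of 52 genes were higher and 21 lower (6 and 22 adjusted over the list alone), with more lower calls than other genes (exact test, adjusted p = 0.00125). The authors' deposited table gives flagellin (BES08_12340, -3.21, adjusted p = 5.6e-43), the filament protein, and the motor stator MotA (BES08_12235, -2.85), whereas a chemotaxis protein CheR (BES08_02825, 2.76) rose. Of mobile elements and phage genes, 39 of 142 genes were higher and 6 lower (39 and 6 adjusted over the list alone), with more higher and fewer lower calls than other genes (exact test, adjusted p = 0.00188 and 4.1e-06), including a pSA3 resolvase (BES08_30330, 3.34) in the authors' deposited table.

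Of the 30 lists, 2 had more higher calls and 10 more lower calls than the other genes, over 60 tests with Benjamini-Hochberg adjustment. Efflux and ABC transport had fewer higher calls than other genes (exact test, adjusted p = 0.00361 and 0.0457), and pili and conjugation fewer lower calls (0.0219). Fisher's test treats genes as independent, which operon neighbours are not: with only the first of neighbouring members kept, glucose catabolism (adjusted p = 0.114), flagellum (0.672) and mobile elements (0.0800) lost their call, and ATP synthase had too few members to test. Against genes of the same replicon the mobile element call was lost too (0.448), and with the authors' own call the aromatic, ribosomal, TCA cycle and flagellum calls remained.

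The comparison of Glc_S with Glc_E asked what changed between exponential and late stationary phase on glucose. In stationary phase, genes for a Tad/Flp pilus, a surface appendage of adhesion, rose from near absence. Several genes of aromatic ring oxygenases rose too, while the protocatechuate genes fell. Per the authors' deposited table, the Flp pilus assembly protein CpaB (BES08_20600, 10.47, adjusted p = 5.5e-140) was listed at 2.22 RPKM in Glc_E and 3479 in Glc_S. Ribosomal protein and ATP synthase genes fell, as did the 8 genes of a cytochrome cbb3 oxidase stretch and 7 genes in 2 stretches of sulfate assimilation. Of 5997 genes, 1188 were higher and 1222 lower (40.2%), and the authors' own call gave 534 and 525.

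All 13 genes from BES08_20540 to BES08_20600 on pSA1 were higher in Glc_S, with a median of 8.22. The first, BES08_20540 (2.19), is annotated as glycogen debranching enzyme GlgX. The authors' deposited table lists TadE (BES08_20555, 9.67), CpaC (BES08_20595, 9.50), TadB (BES08_20580, 9.01), CpaF (BES08_20585, 8.96), a histidine kinase (BES08_20590, 8.79) and a further pilus assembly protein (BES08_20560, 8.22). Of the aromatic degradation list, 22 of 52 genes were higher and 7 lower (22 and 7 adjusted over the list alone), more higher calls than among other genes (exact test, adjusted p = 9.6e-04, and 0.0751 with the authors' own call). In the authors' deposited table these were led by pSA1 genes: the benzoate 1,2-dioxygenase small subunit (BES08_19585, 6.56, adjusted p = 1.7e-20), its large subunit (BES08_19590, 4.58), a ring-hydroxylating oxygenase alpha subunit (BES08_18230, 4.63) and catechol 1,2-dioxygenase (BES08_19595, 4.51). The 6 genes of the pSA3 oxygenase stretch were all higher, by 1.37 to 3.34, whereas 4 of the 15 sulfocatechol genes were. All 6 genes of the pSA1 protocatechuate stretch were lower, at -3.93 to -2.77. Isocitrate lyase, which opens the glyoxylate shunt, rose by 3.82 (BES08_08870) in the authors' deposited table, and a pSA3 malate dehydrogenase (BES08_29845, 4.17) rose too. Of mobile elements and phage genes, 40 of 142 genes were higher and 10 lower (40 and 7 adjusted over the list alone); the excess of higher calls (exact test, adjusted p = 0.0496) was lost at equal RPKM sums (0.159) and within replicons (0.280). The authors' deposited table lists a pSA3 transposase (BES08_30955, 5.01) among them. For nitrogen, the authors' deposited table lists a urea carboxylase-associated protein of pSA2 (BES08_26220, 6.34, adjusted p = 3.1e-51), another of pSA1 (BES08_21615, 6.13) and a glutamate synthase (BES08_14985, 3.62).

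Translation genes fell in stationary phase on glucose. Of ribosomal proteins, 0 of 53 genes were higher and 51 lower (0 and 51 adjusted over the list alone), with a median of -3.67. The authors' deposited table lists 30S ribosomal protein S17 (BES08_09230, -5.74, adjusted p = 1.6e-41), 50S L30 (BES08_09185, -5.47), L9 (BES08_01790, -5.44) and L3 (BES08_09275, -5.32). Aminoacyl-tRNA synthetases counted 0 higher and 21 lower of 21 (0 and 21 adjusted over the list alone), translation factors 0 higher and 14 lower of 16 (0 and 15 adjusted over the list alone) and the RNA polymerase list 0 higher and 7 lower of 12 (0 and 7 adjusted over the list alone). In the authors' deposited table these included glutamate tRNA ligase (BES08_11230, -3.79) and elongation factor Ts (BES08_01205, -4.43). Of chaperones and proteases, 1 of 27 genes were higher and 17 lower (2 and 20 adjusted over the list alone), with HslU (BES08_23725, -4.78) and ClpB (BES08_08320, -3.22) in the authors' deposited table. Cell division and DNA replication genes counted 8 higher and 26 lower of 73 (8 and 27 adjusted over the list alone), with the rod shape protein MreC (BES08_03660, -3.90) in the authors' deposited table. Without wrongly matched products this list counted 3 higher and 17 lower of 39. Lower calls were enriched in these 6 lists, with adjusted p of 1.3e-31, 8.1e-14, 2.4e-07, 0.0185, 1.7e-05 and 0.0138. Within replicons the call of the RNA polymerase list (random draws, adjusted p = 0.188) and that of cell division (0.152) were lost.

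Energy genes fell alongside. Of ATP synthase genes, 0 of 8 genes were higher and 8 lower (0 and 8 adjusted over the list alone), and of the respiratory chain 6 higher and 26 lower of 39 (6 and 26 adjusted over the list alone) (exact test, adjusted p = 2.5e-05 and 8.9e-09 for lower calls). The authors' deposited table gives the ATP synthase epsilon subunit (BES08_05300, -4.92, adjusted p = 3.5e-09) and subunit gamma (BES08_05290, -4.38). A cytochrome cbb3 oxidase gene (BES08_12890), part of a terminal oxidase with high oxygen affinity, was at 6734 RPKM in Glc_E and listed at 0 in Glc_S in the authors' deposited table. All 8 genes of its stretch were lower, among them accessory protein CcoG (BES08_12880, -6.23) in the authors' deposited table. The 6 other lowest named genes of the authors' deposited table, all listed at 0 in Glc_S, were a hydrolase (BES08_13655), an acetyl-CoA carboxylase carrier protein (BES08_00765), a peptidase S41 (BES08_20005), DnaJ (BES08_15330), precorrin-8X methylmutase (BES08_17760) and the tRNA-modifying subunit TsaB (BES08_08190). Of the TCA cycle list, 2 of 20 genes were higher and 15 lower (2 and 15 adjusted over the list alone) (exact test, adjusted p = 2.6e-06), including fumarate hydratase (BES08_13705, -3.27) in the authors' deposited table. Of glucose catabolism, 9 of 40 genes were higher and 15 lower (9 and 16 adjusted over the list alone), which did not pass (exact test, adjusted p = 0.0503) and was called in 8 alternatives.

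Of sulfur metabolism in Glc_S, 6 of 29 genes were higher and 6 lower (6 and 6 adjusted over the list alone), and of nitrogen metabolism 5 higher and 8 lower of 29 (5 and 8 adjusted over the list alone); neither passed (lowest adjusted p by the exact test 0.893 and 0.531). Sulfate assimilation fell in the authors' deposited table, with adenylyl-sulfate kinase (BES08_04945, -4.94, adjusted p = 9.6e-32), phosphoadenosine phosphosulfate reductase (BES08_00825, -4.59) and sulfite reductase (BES08_00835, -3.99). Of flagellum genes, 5 of 52 genes were higher and 18 lower (6 and 18 adjusted over the list alone) (exact test, adjusted p = 0.0496, lost within replicons at 0.256), including the M-ring protein FliF (BES08_12125, -3.28) in the authors' deposited table. Flagellin itself (BES08_12340) was at 0.12 with adjusted p = 0.780 in the authors' deposited table. Of ABC transport genes, 10 of 90 genes were higher and 31 lower (12 and 33 adjusted over the list alone) (exact test, adjusted p = 0.0106, and 0.106 within replicons). Toxin-antitoxin genes, pili and mobile elements had fewer lower calls than other genes (exact test, adjusted p = 0.0340, 5.0e-05 and 1.1e-04). Of the 30 lists, 2 had more higher and 11 more lower calls than other genes. With only the first of neighbouring members kept, calls were lost by the RNA polymerase list (exact test, adjusted p = 0.0575), cell division (0.0538), flagellum (1.00), ABC transport (0.122) and mobile elements (0.432), and ATP synthase had too few members to test.

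The comparison of SA_S with SA_E asked the same of cells on sulfanilic acid. Most sulfocatechol genes fell, and stretches of genes for catechol, phenylalanine and histidine breakdown rose. As listed in the authors' deposited table, a glyoxalase (BES08_15890, 9.45, adjusted p = 1.7e-173) went from 37.8 to 26509.8 RPKM, and catechol 1,2-dioxygenase (BES08_19595, 6.52, adjusted p = 1.4e-69) from 15.3 to 1455. Ribosomal, ATP synthase and NADH dehydrogenase genes fell. Of 5997 genes, 1112 were higher and 1334 lower (40.8%), and the authors' own call gave 370 and 438. With equal RPKM sums the counts were 764 and 1708, so that the share of higher calls went from 45.5% to 30.9%.

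Of the 15 sulfocatechol genes of pSA3, 13 were lower in SA_S and none was higher, and the share of the stretch in the RPKM went from 6.79% to 0.902%. The authors' deposited table lists maleylacetate reductase (BES08_30505, -4.27, adjusted p = 2.1e-94), 4-sulfomuconolactone hydrolase (BES08_30500, -3.83) and sulfocatechol 3,4-dioxygenase alpha subunit (BES08_30520, -1.98). Of the oxygenase stretch of pSA3, 2 genes rose and 2 fell: in the authors' deposited table, ferredoxin (BES08_30690, 1.87) rose, and the oxygenase alpha subunit (BES08_30725) was at -0.15 with adjusted p = 0.552. The transposase of this stretch (BES08_30705, -1.80) was among the genes that fell. All 11 genes of the pSA1 amidohydrolase stretch were lower, with the monooxygenase (BES08_23655, -7.77), GlcG (BES08_23660, -7.47) and the isomerase (BES08_23670, -6.17) in the authors' deposited table. All 7 genes of the pSA1 catechol stretch were higher, including muconolactone delta-isomerase (BES08_19600, 6.59), the benzoate dioxygenase large subunit (BES08_19590, 6.07), muconate cycloisomerase (BES08_19605, 5.72) and a benzoate diol dehydrogenase (BES08_19580, 5.72) in the authors' deposited table. Of the aromatic degradation list, 17 of 52 genes were higher and 14 lower (17 and 14 adjusted over the list alone). Its excess of higher calls (exact test, adjusted p = 0.0480) was lost in 6 alternatives. There the adjusted p went from 0.0674 to 0.250 (exact test, or random draws for any test within replicons). Its median went from 0.39 to -0.03 at equal RPKM sums.

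Some genes of amino acid breakdown, which no fixed list covers, rose in SA_S. In the authors' deposited table, a fused regulator and proline dehydrogenase (BES08_00805, 5.82, adjusted p = 1.1e-88) was among the highest. After their values were seen, 2 stretches were picked: 5 chromosomal genes around phenylalanine breakdown (BES08_10030 to BES08_10050) and 5 pSA1 genes of histidine utilisation (BES08_19750 to BES08_19770), all 10 higher. The authors' deposited table gives phenylalanine 4-monooxygenase (BES08_10050, 4.86), 4-hydroxyphenylpyruvate dioxygenase (BES08_10045, 4.48), imidazolonepropionase (BES08_19755, 5.40) and histidine ammonia-lyase (BES08_19760, 4.16). In Glc_S against Glc_E, 4 of the 5 phenylalanine genes were higher too and 1 was lower, while 0 histidine genes were called. Of the 7 genes of the catechol stretch, 6 were higher there. In SA_S, the glyoxylate shunt enzyme isocitrate lyase (BES08_08870) rose by 4.06 in the authors' deposited table. Of TonB-dependent transport, 28 of 94 genes were higher and 21 lower (31 and 21 adjusted over the list alone); the excess of higher calls (exact test, adjusted p = 0.0311) was lost at equal RPKM sums (0.223). The authors' deposited table lists a pSA1 receptor (BES08_19675, 4.16) and energy transducer TonB (BES08_09500, 3.45) as higher, and the pSA1 receptor of the amidohydrolase stretch (BES08_23675, -5.65) as lower. Of mobile elements, 38 of 142 genes were higher and 15 lower (38 and 15 adjusted over the list alone), which did not pass for higher calls (exact test, adjusted p = 0.0587) but had fewer lower calls (0.00304). Without a wrongly matched product it passed for higher calls (exact test, adjusted p = 0.0464), as it did with the median fold change set to 0 (0.0188).

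Translation and energy genes fell. Of ribosomal proteins, 0 of 53 genes were higher and 47 lower (1 and 50 adjusted over the list alone), with a median of -3.02; the authors' deposited table lists 30S ribosomal protein S19 (BES08_09255, -6.07, adjusted p = 6.8e-33), S7 (BES08_09300, -5.46), S14 (BES08_09210, -5.36) and L7/L12 (BES08_14785, -5.19). Synthetases counted 0 higher and 19 lower of 21 (0 and 19 adjusted over the list alone), translation factors 0 higher and 13 lower of 16 (0 and 13 adjusted over the list alone) and the RNA polymerase list 1 higher and 7 lower of 12 (1 and 7 adjusted over the list alone). Per the authors' deposited table, serine tRNA ligase (BES08_08665, -2.19), elongation factor Ts (BES08_01205, -3.85) and RNA polymerase alpha (BES08_09145, -3.72) fell, while another gene annotated as RNA polymerase alpha (BES08_06395, 2.32) rose. Of ATP synthase genes, 0 of 8 genes were higher and 7 lower (0 and 7 adjusted over the list alone), and of the respiratory chain 2 higher and 23 lower of 39 (3 and 23 adjusted over the list alone). The authors' deposited table lists ATP synthase subunit delta (BES08_05280, -4.77, adjusted p = 8.9e-20), NADH-quinone oxidoreductase subunit N (BES08_03140, -3.76) and subunit L (BES08_03130, -3.75). Genes listed at 0 in SA_S in the authors' deposited table were NADH-quinone oxidoreductase subunit K (BES08_03125), ATP synthase epsilon (BES08_05300), the septum formation protein Maf (BES08_04790) and a globin (BES08_13795, 325 RPKM in SA_E). Lower calls were enriched in these 6 lists, with adjusted p of 3.6e-23, 1.4e-09, 1.3e-05, 0.0311, 0.00147 and 1.3e-05; within replicons the RNA polymerase call was lost (0.229).

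Of the TCA cycle list, 2 of 20 genes were higher and 10 lower (2 and 10 adjusted over the list alone) (exact test, adjusted p = 0.0290), a call lost once wrongly matched products were removed (0.112). The authors' deposited table lists isocitrate dehydrogenase (BES08_07705, -2.84, adjusted p = 4.6e-25) and a succinate dehydrogenase membrane subunit (BES08_07865, -3.27). Of chaperones and proteases, 3 of 27 genes were higher and 17 lower (3 and 19 adjusted over the list alone) (exact test, adjusted p = 7.3e-05), with an Hsp70 chaperone (BES08_19930, -4.23) and HslU (BES08_23725, -3.96) in the authors' deposited table. Of cell division genes, 11 of 73 genes were higher and 28 lower (11 and 29 adjusted over the list alone) (exact test, adjusted p = 0.00992, lost within replicons at 0.174), including DNA polymerase III subunit chi (BES08_05530, -3.45) in the authors' deposited table. Without wrongly matched products the cell division list counted 5 higher and 22 lower of 39. Of sulfur metabolism, 3 of 29 genes were higher and 5 lower (3 and 5 adjusted over the list alone), and of nitrogen metabolism 2 higher and 8 lower of 29 (2 and 7 adjusted over the list alone), and neither passed (lowest adjusted p by the exact test 0.553 and 0.286). As listed in the authors' deposited table, alkanesulfonate monooxygenase (BES08_16775, 1.58), which frees sulfite from sulfonates, and a taurine catabolism dioxygenase (BES08_07710, 1.44) rose, and glutamate synthase (BES08_13150, -3.28, adjusted p = 5.9e-39) fell. Toxin-antitoxin genes and pili had fewer lower calls (exact test, adjusted p = 0.0267 and 0.00304). Of the 30 lists, 2 had more higher and 9 more lower calls than other genes. With neighbouring members thinned, aromatic degradation (exact test, adjusted p = 0.250) and cell division (0.112) lost their call, and ATP synthase was not testable.

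**Figure D3:**
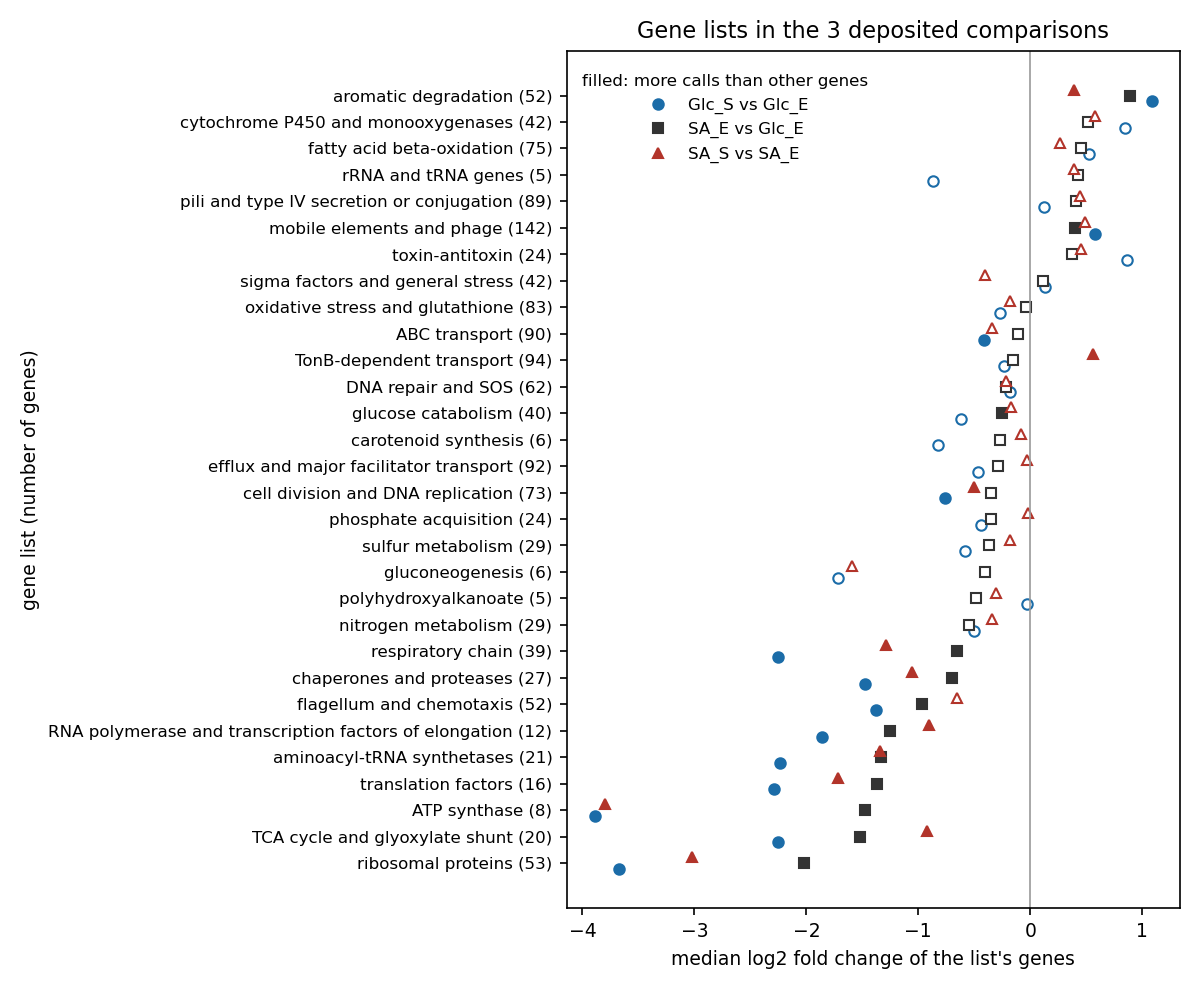
The median log2 fold change of each of the 30 gene lists in the 3 deposited comparisons; filled points mark lists with more calls in that direction than other genes (Fisher's exact test, adjusted over 60 tests). Ribosomal proteins lie at -3.67, -2.02 and -3.02; under other scalings the medians of 8 points near 0 change sign, that of aromatic degradation in SA_S against SA_E from 0.39 to -0.03.

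The remaining lists, as fixed, had no excess of calls in any comparison and are given once, in the order SA_E against Glc_E, Glc_S against Glc_E, SA_S against SA_E, all from the authors' deposited tables. Gluconeogenesis counted 1 higher and 2 lower of 6 (1 and 2 adjusted over the list alone), then 2 and 4 (2 and 4), then 1 and 4 (1 and 4). Fatty acid beta-oxidation counted 11 higher and 11 lower of 75 (9 and 11 adjusted over the list alone), then 18 and 9 (18 and 9), then 20 and 9 (20 and 9). Pili and conjugation counted 19 higher and 7 lower of 89 (19 and 7 adjusted over the list alone), then 19 and 3 (18 and 3), then 14 and 7 (14 and 7). Efflux counted 4 higher and 23 lower of 92 (4 and 21 adjusted over the list alone), then 11 and 23 (11 and 23), then 15 and 17 (14 and 17). Oxidative stress and glutathione counted 14 higher and 22 lower of 83 (14 and 23 adjusted over the list alone), then 25 and 25 (25 and 25), then 17 and 27 (17 and 27). Sigma factors counted 10 higher and 5 lower of 42 (10 and 5 adjusted over the list alone), then 10 and 8 (10 and 8), then 10 and 13 (10 and 13). Toxin-antitoxin genes counted 5 higher and 1 lower of 24 (4 and 1 adjusted over the list alone), then 7 and 0 (7 and 0), then 8 and 0 (8 and 0). Polyhydroxyalkanoate genes counted 0 higher and 3 lower of 5 (0 and 3 adjusted over the list alone), then 0 and 2 (0 and 2), then 0 and 0 (0 and 0). Phosphate acquisition counted 2 higher and 9 lower of 24 (2 and 9 adjusted over the list alone), then 5 and 6 (5 and 6), then 6 and 3 (6 and 3). DNA repair and SOS counted 8 higher and 15 lower of 62 (8 and 15 adjusted over the list alone), then 17 and 16 (17 and 18), then 10 and 17 (10 and 18). Without wrongly matched products it counted 1 higher and 8 lower of 34, then 8 and 7, then 3 and 9. Carotenoid synthesis counted 0 higher and 0 lower of 6 (0 and 0 adjusted over the list alone), then 1 and 3 (1 and 3), then 2 and 2 (2 and 3). Cytochrome P450 and monooxygenases counted 5 higher and 5 lower of 42 (5 and 5 adjusted over the list alone), then 10 and 5 (10 and 5), then 12 and 4 (12 and 4). Ribosomal RNA and tRNA genes counted 0 higher and 1 lower of 5 (0 and 1 adjusted over the list alone), then 0 and 1 (0 and 1), then 0 and 2 (0 and 2). Of these, oxidative stress genes in Glc_S did not pass for higher calls (exact test, adjusted p = 0.0725) and were called in 6 alternatives. Phosphate acquisition in SA_E had more lower calls once wrongly matched products were removed (exact test, adjusted p = 0.0321), and in 2 rescalings. With a minimum log2 fold change of 1, calls were gained by pili in SA_E for higher genes (exact test, adjusted p = 0.0478), and by gluconeogenesis in Glc_S (0.0425) and oxidative stress in SA_S (0.0486) for lower genes. Other lists lost calls under this setting, and the calls that remained are counted further below. Lists with calls elsewhere but none here counted as follows: cell division 5 higher and 20 lower of 73 (5 and 20 adjusted over the list alone) and ABC transport 6 higher and 23 lower of 90 (6 and 23 adjusted over the list alone) in SA_E; TonB-dependent transport 18 higher and 25 lower of 94 (18 and 26 adjusted over the list alone) in SA_E and 20 higher and 22 lower of 94 (20 and 23 adjusted over the list alone) in Glc_S. In SA_S, glucose catabolism counted 4 higher and 10 lower of 40 (4 and 10 adjusted over the list alone), flagellum genes 5 higher and 16 lower of 52 (5 and 16 adjusted over the list alone) and ABC transport 11 higher and 27 lower of 90 (11 and 27 adjusted over the list alone). Without wrongly matched products, cell division in SA_E counted 3 higher and 10 lower of 39.

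The phase changes on the 2 substrates were compared across genes, which are not independent replicates. Fold changes of SA_S against SA_E and of Glc_S against Glc_E correlated with Pearson's r = 0.445 (95% bootstrap interval over genes 0.421 to 0.468) and a Spearman rank correlation of 0.493. Higher in both were 593 genes, against 220 if the calls were unrelated, and lower in both 782, against 272; the latter held ribosomal, ATP synthase and cytochrome cbb3 genes. Called in opposite directions at the same threshold were 117 genes. Of these, 78 rose on glucose and fell on sulfanilic acid, against 264 if the calls were unrelated, and 39 did the reverse, against 227. A stricter test that needs both changes (the larger p of each gene, adjusted) passed 46 opposite genes: 30 rose on glucose and fell on sulfanilic acid, and 16 did the reverse. The fructose PTS subunit (BES08_21275) was at -3.72 on glucose and 4.71 on sulfanilic acid in the authors' deposited table, and 4-hydroxybenzoate 3-monooxygenase (BES08_24955) at -3.53 and 2.95. The pSA3 molybdopterin oxidoreductase (BES08_29795) was at 4.35 and -2.74 in the authors' deposited table, the pSA1 amidohydrolase (BES08_23650) at 2.52 and -4.04. A normal approximation of the difference between the changes, added after the data were seen, called 1046 genes, 409 with a more positive change on sulfanilic acid and 637 with a more negative one; it cannot call the 1151 genes whose adjusted p was listed as 1. Among the called genes were 10 of aromatic degradation with a more positive and 16 with a more negative change on sulfanilic acid. Of ribosomal protein genes, 14 had a more positive change, which was a smaller fall, and 1 a more negative one. The Tad pilus gene CpaB (BES08_20600) rose on glucose, and its value on sulfanilic acid was 0.95 with adjusted p = 0.297 in the authors' deposited table, with an adjusted p of 3.4e-29 for the difference.

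No deposited comparison sets SA_S against Glc_S, so their substrate difference is described by RPKM ratios (log2, 1 added to each RPKM) with no test. The RPKM columns of Glc_E and SA_E were identical in the tables that share them. Glc_S and SA_S each occur in a single comparison, so a common scale for them is assumed and was not tested. Their RPKM sums were 1372887 and 1565496. Of 5931 genes with at least 1 RPKM in either group, 473 were at least 4-fold higher in SA_S and 363 at least 4-fold lower. This balance turned round with equal RPKM sums, at 414 and 468, and with genes at 0 in either group left out, at 206 and 267. The glyoxalase BES08_15890 was at 6.99, histidine ammonia-lyase (BES08_19760) at 4.85 and the fused proline dehydrogenase (BES08_00805) at 4.46, from RPKM of the authors' deposited table. The Tad pilus genes were lower in SA_S, with -7.01 for CpaB (BES08_20600) and -7.30 for CpaC (BES08_20595), and flagellin (BES08_12340) was at -4.37, from the same columns of the authors' deposited table. Sulfocatechol genes were higher in SA_S, with 2.21 for the cycloisomerase (BES08_30495) and 1.59 for the dioxygenase alpha subunit (BES08_30520) from the authors' deposited table. List medians were 0.48 for aromatic degradation, -1.21 for ribosomal proteins, -1.40 for ATP synthase and -0.70 for the respiratory chain, against -0.02 for all genes.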

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

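The results here were flagged because the change from exponential to stationary phase went opposite ways on the 2 substrates, by the test of both directions, of which 46 genes passed. The genes named were chosen by size after the test. Per the authors' deposited table, the fructose PTS subunit IIBC (BES08_21275) changed by -3.72 on glucose and 4.71 on sulfanilic acid, and 1-phosphofructokinase beside it (BES08_21270) by -6.55 and 2.34. The amino acid dehydrogenase (BES08_00560) was at -3.56 and 2.34 in the authors' deposited table, and 4-hydroxybenzoate 3-monooxygenase (BES08_24955) at -3.53 and 2.95. These 4 genes were also lower in SA_E than in Glc_E. The molybdopterin oxidoreductase (BES08_29795) went the other way, at 4.35 and -2.74, as did the pSA1 amidohydrolase (BES08_23650), at 2.52 and -4.04 in the authors' deposited table. Both were higher in SA_E than in Glc_E. No technical explanation was tested for these genes, and no biological one.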

How the results depend on the processing

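No paired analysis was possible because the files hold no value per library. For the same reason the planned library-size normalizations, count filters, other model fits, leave-one-out fits, list tests with an estimated correlation and the fit without ribosomal and transfer RNA genes were not run. Of the alternative values for the main results, 125 stayed within 1.5 times the reported count or within its interval and 27 moved. Nearly all are counts, which cannot change sign, but which side had more genes did change in Glc_S against Glc_E, in SA_E against Glc_E and between SA_S and Glc_S, as given here. Most alternatives were added after the data were seen. Counts of called genes stayed within 1.5 times the reported ones with an adjusted p of 0.01, a minimum log2 fold change of 1 and filters on RPKM. Within that limit, higher genes in SA_E against Glc_E went from 951 to 704 at 0.01. Lower genes of the same comparison went from 1126 to 788 at the log2 minimum.

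The authors' own call, which by construction asks for larger changes, gave 534 higher and 525 lower genes in Glc_S, 256 and 181 in SA_E and 370 and 438 in SA_S. In SA_E this moved the share of higher calls from 45.8% to 58.6%. It left 79 higher pSA3 genes, 9 genes of opposite phase change, and 4 list calls each in SA_E against Glc_E and SA_S against SA_E. With RPKM sums made equal, the split in SA_S against SA_E went from 1112 higher and 1334 lower to 764 and 1708, or to 673 and 1668 with every standard error floored. The split in Glc_S was then 1036 and 1357, and in SA_E 1015 and 1071. Which scaling is right was not tested.

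Genes of opposite phase change numbered 28 with the median set to 0 and errors floored, and 66 with equal sums, 41 of them among the 46 reported. The normal approximation, which counts any difference rather than opposite signs, gave 1046, or 935 with errors floored. The correlation of the phase changes was 0.481, 0.400 and 0.532 from RPKM ratios with pseudocounts of 1, 0.1 and 5, and 0.529 at 10 RPKM or more. It was 0.531 with genes at 0 left out; the cause was not tested. Between SA_S and Glc_S, the reported 473 higher and 363 lower genes became 198 and 224 with a pseudocount of 5, 206 and 267 with genes at 0 left out, and 414 and 468 with equal sums. A 2-fold limit, which by construction takes in more genes, gave 1177 and 1221. Which side has more genes thus depends on the processing.

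With the first of neighbouring members alone, 7 of 13 list calls remained in Glc_S against Glc_E, 8 of 12 in SA_E against Glc_E and 8 of 11 in SA_S against SA_E; fewer genes were tested. Within replicons 8 remained in Glc_S against Glc_E and 7 in SA_S against SA_E; the cause was not tested. At an adjusted p of 0.01, 9 of 13 list calls remained in Glc_S against Glc_E, 12 of 12 in SA_E against Glc_E and 9 of 11 in SA_S against SA_E. With a minimum log2 fold change of 1, 11, 11 and 8 remained in that order. Of 249 results for named genes none changed sign while called; 14 lost their call at 0.01, 3 at a log2 fold change of 1, 39 under the authors' own call, 1 with the median set to 0, and 5 and 6 with floored errors under equal sums and under the median. The lower estimated depth of the stationary groups limits weakly expressed genes: a single read of a 900-base gene was worth 2.95 RPKM in Glc_S and 2.10 in SA_S.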

Other observations

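All tests in this part were chosen and written after the patterns were seen, and 4 of them replaced earlier tests whose values had been seen. The rise of pSA3 genes on sulfanilic acid in exponential phase was set against 3 technical explanations. Without the 3 catabolic stretches and the 20 most abundant genes, 47.7% of 285 pSA3 genes were still higher, against 17.7% of genes on the other plasmids (Fisher's exact test, p = 4.5e-27). With 164 of 314 genes higher, leaving out so few could not have lowered the share much. The test thus restates that count, which by itself shows that a few abundant genes are not the whole cause. To give the median rise in RPKM alone, residual plasmid DNA would have to add 33.5 RPKM to every gene, and 25.2% of pSA3 genes lay below that level in SA_E. A smaller contribution of plasmid DNA is not excluded by this. A common factor for the plasmid, such as its copy number, could underlie the rise and stays open. For 52.9% of pSA3 genes the plasmid median lay outside the 95% interval of their fold change, but so did the chromosome median for 42.9% of its genes.

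Cells growing on sulfanilic acid and stationary cells on glucose departed from Glc_E in like directions. Of the genes called in SA_E against Glc_E, 65.9% were called the same way in Glc_S against Glc_E. This was 534 genes higher in both, against 188 if the calls were unrelated, and 834 lower in both, against 229. The numbers for unrelated calls take no account of the shared Glc_E cultures. SA_E and Glc_S were not tested against each other, and some stretches differed widely between them. The median RPKM of the Tad pilus stretch was 9.41 in SA_E and 1145 in Glc_S. Both comparisons share the Glc_E cultures, and simulated noise, shared as far as the fitted errors allow, gave a mean covariance of 0.610, with a 95% range up to 0.703, where 1.77 was observed. Among the 3777 genes at 10 RPKM or more in every group, the covariance was 1.37, against a bound of 0.149 for shared noise. The simulated r had a mean of 0.450 and a range up to 0.502, where 0.596 was observed. The simulation held noise and no change of any gene, so its r cannot be set against the observed one. The observed r had a bootstrap interval over genes of 0.574 to 0.617. A wrong scale that adds 1 constant to all fold changes of a comparison leaves r unchanged, so such a scale is not its cause. This follows from how r is computed and was not tested by the interval. Counts of genes called alike can still move with the scale. The authors' normalization is not stated, so an error that differs between genes stays open. A lower growth rate on sulfanilic acid, or a trait of both Glc_E cultures, might give the same pattern, and no growth rate is in the sources used here.

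Of the 366 genes listed at 0 in Glc_S, 234 had under 10 RPKM in Glc_E, where the estimated depth alone allows 369 for genes of 900 bases, so low depth can account for these. A further 68 genes at 0 had 20 RPKM or more in Glc_E, where depth alone would give 0.173 if all genes were unchanged and 900 bases long. Of these, 12 were lower by a Bonferroni bound over all tested genes, which allows 0.05 false genes however they are picked, so low depth alone does not account for those 12; for the others this rests on the assumed length. For 3424 genes at 20 RPKM or more in Glc_E, both neighbours were above 0 in Glc_S. At 900 bases, 13.6 of them would be at 0 had each changed as its neighbours, and 54 were. Asking for neighbours above 0 leaves out those that fell furthest, which lowers the 13.6, so the excess may be overstated. The cbb3 oxidase gene BES08_12890 would have 24.8 reads at 900 bases, or 4.13 at 150 bases, had it changed as its neighbours. Zeros at such levels were not limited to Glc_S: 36 genes at 20 RPKM or more in SA_E were listed at 0 in SA_S. There 0.00916 would be at 0 if all genes were unchanged and 900 bases long. Gene lengths are not given in the sources used here, so a loss of short transcripts in stationary phase stays untested.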
